A study of Bradyrhizobium sp. ORS 285 with 9 samples.

How the data were processed

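Wild-type Bradyrhizobium sp. ORS285 was measured by strand-specific total RNA sequencing on a SOLiD 5500XL with 50 bp reads, per the labels' protocols. Plant and bacterial ribosomal RNA and eukaryotic messenger RNA had been depleted from nodule RNA, per the labels. There were 3 groups of 3 libraries each: a culture in YM medium at an OD600 of 0.5, whole nodules of A. afraspera (E-type bacteroids) and whole nodules of A. indica (S-type bacteroids), from plants kept at 28 °C and sampled after 14 days. Culture RNA came from a hot phenol and SDS extraction and nodule RNA from another method, per the labels, so extraction method and state cannot be told apart in comparisons with culture.

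The deposited files hold counts of reads per gene, as whole numbers, in a column of reads mapped to 1 place and a column of all gene reads, per the file headers. The aligner, its version, the genome build and the source of the annotation are not given in the sources used here. Each file covers 6983 coding genes with their positions and coding lengths, of which 1382 have a symbol and 5601 a locus tag only. Of the 9 files 1 holds no gene names and was joined to the rest by position. The reads mapped to 1 place were used, and the column of all gene reads served as an alternative. Reads mapped to more than 1 place were 1.83% to 2.9% of a library. Genes with near-identical copies, nifH_1 and nifH_2 among them, are therefore uncertain.

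Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, in 1 fit over all 9 libraries with 6 residual degrees of freedom. Genes were filtered with filterByExpr by group, which left 6667 genes and removed 316. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors were taken from the fold change and the test statistic and are approximate. The common biological coefficient of variation was 0.215. There were 3 pairwise comparisons and a comparison of the mean of both bacteroid types with culture. Ratios of genes with 1 to 3 reads in a group carry a 95% counting interval.

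Gene lists were matched by symbol, and 27 of 31 lists had members, with 534 genes in at least 1 list. The lists cover nitrogenase, microaerobic respiration, nodulation, photosynthesis, the Calvin cycle, hydrogenase, dicarboxylate uptake and the tricarboxylic acid cycle, nitrogen regulation, polyhydroxybutyrate, flagella, chemotaxis, ribosomal proteins, ATP synthase and complex I, cell division, peptidoglycan, hopanoids, secretion types III, IV and VI, chaperones, reactive oxygen, general stress response, amino acids, nucleotides, iron and haem, denitrification, polysaccharides and efflux. Lists for peptide transporters of the BacA kind and for mobile elements matched no symbol. The list for secretion types IV and VI matched only trb genes, so type VI secretion was not covered. Lists for uptake transporters and regulators were defined by product names only, which were not available, so they could match no gene. Each list was tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over lists of at least 3 tested members. The hopanoid list had 1 member and was not tested this way. Genes named in the text are the 8 largest changes per direction with a symbol, at least 50 CPM in the higher group and groups that do not overlap, up to 4 called members per list and comparison with at least 20 CPM, or the most highly expressed member of a list with no call, and a fixed set of symbiosis and housekeeping genes. This took 202 genes.

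The groups, tests, gene lists, naming rule and alternatives other than the count of all gene reads were chosen before the data were examined. Alternatives were DESeq2 size factors, total counts, no filter, a filter of 50 CPM in 3 libraries, the DESeq2 1.42.0 test, limma-voom, fits of only the groups compared, a fit with the replicate number as a block (the replicate block), thinning to the shallowest library, a stricter threshold (adjusted p under 0.01 and a log2 fold change of 1.5), and leaving out each library in turn. Shared calls were set beside 20 simulations of unchanged groups. The edgeR test was run on simulated counts with 200 changed genes. At 4-fold it recovered 93.9% of the changed genes for E-type against culture (6466 genes run), 100% for S-type against culture (6469) and 100% between bacteroid types (6594), at 2-fold 59.7%, 52.2% and 64.2%, and at 1.5-fold 9%, 11.9% and 7.5%. False calls were 6.1%, 4.4% and 5.8% of the calls, and for DESeq2 17.8%, 9.8% and 11.3%. The 200 genes were changed evenly up and down, by at most 4-fold. In the data 63.7%, 69.6% and 38.3% of genes were called, some with far larger changes. The simulated shares of false calls may therefore not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.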

Results

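Transcripts of Bradyrhizobium sp. ORS285, a photosynthetic nitrogen-fixing soil bacterium, were counted in 3 states. The first was a free-living culture in rich YM medium, collected at an OD600 of 0.5. The other states were those inside whole nodules of 2 legumes of the genus Aeschynomene, collected 14 days after inoculation. Nodules of A. afraspera hold elongated E-type bacteroids, and nodules of A. indica hold spherical S-type bacteroids. Bacteroids are the differentiated intracellular form of the bacterium. Each group had 3 libraries, 9 in all. The comparisons address how bacterial expression in nodules departs from that of free-living cells, and how it differs between the 2 bacteroid types. Each bacteroid type came from whole nodules of 1 host species only. Host species, nodule and bacteroid type therefore cannot be told apart. Each library gave read counts for 6983 protein-coding genes. Uniquely placed reads per library came to 3369708, 5488053 and 2371301 in culture, 7235861, 4289549 and 5605991 in E-type nodules, and 14734588, 6598401 and 3375408 in S-type nodules. The labels number the replicates without saying that they came from separate cultures or plants, so p-values measure only the spread between these samples, which may be technical. Adjusted p-values below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at a threshold of 0.05, over 6667 genes, and n = 3 per group throughout. Levels are normalised CPM (read counts scaled to library size), as mean ± SD. Fold changes are on the log2 scale, ± SE. Positions are those of the single sequence the files use, whose build is not given in the sources used here.

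The 3 states were far apart compared with their replicates. The first principal component held 80.9% of the variance and placed culture against nodules, and the second held 11.5% and placed E-type against S-type nodules. Pearson correlations across genes were 0.965 to 0.989 between libraries of the same group. They were 0.891 to 0.919 between E-type and S-type nodules, 0.623 to 0.655 between culture and E-type nodules, and 0.554 to 0.586 between culture and S-type nodules. Genes are not independent replicates. The nitrogenase structural genes nifH, nifD and nifK took 8.23% to 13.89% of the reads in E-type nodules and 10.17% to 12.2% in S-type nodules, against 0.0023% to 0.0029% in culture.

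**Figure D1:**
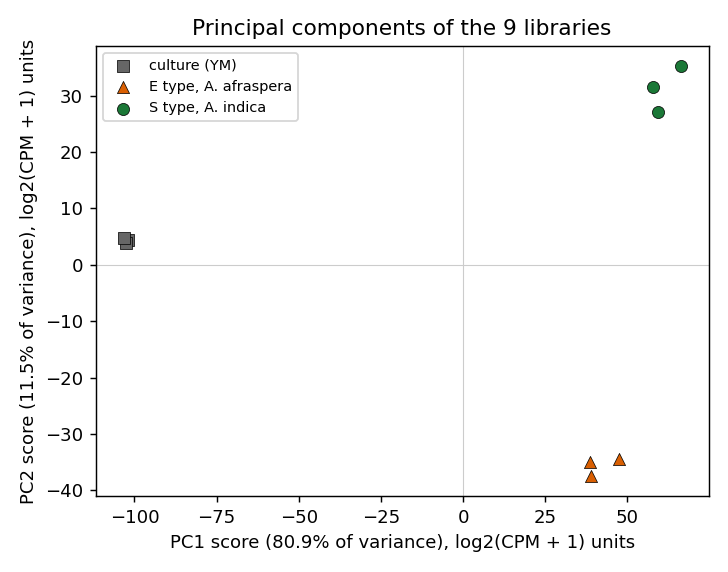
Scores of the 9 libraries on the first (x axis, 80.9% of the variance) and second (y axis, 11.5%) principal components of log2(CPM + 1), 1 point per library, coloured by group. The 3 culture libraries lie between -103.3 and -102.1 on the first axis, all nodule libraries lie at 38.6 or above, and the second axis sets E-type libraries (-37.4 to -34.4) apart from S-type libraries (27.1 to 35.2).

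The first comparison asked what E-type bacteroids in A. afraspera nodules express relative to free-living cells. The nitrogen fixation genes rose. In uniquely placed reads, with the nifH copies counted apart, nifD had the highest mean CPM of all genes tested. All 20 tested members of the nitrogenase list rose, by a median log2 fold change of 11.5. nifD, which encodes the alpha subunit of the molybdenum-iron protein (positions 1721846 to 1723348, plus strand), went from 10.6 ± 1.70 CPM in culture to 54680 ± 19230 CPM, a log2 fold change of 12.35 ± 0.49 (adjusted p = 8.32e-09). nifK, for the beta subunit (1723444 to 1725003, plus strand), rose by 11.42 ± 0.45, and nifB, needed to build the cofactor, by 12.61 ± 0.46. fixA, fixB and fixC, whose products pass electrons to nitrogenase, rose by 12.84, 12.9 and 12.68. The activator gene nifA rose by 4.6 ± 0.39, from 5.77 to 144 CPM. The 2 copies of nifH, for the dinitrogenase reductase, also drew reads that map to more than 1 place, which unique counts leave out, so their levels and the split between them are uncertain. nifH_1 (1720882 to 1721769) reached 30110 ± 8721 CPM and nifH_2 (1749336 to 1750223) reached 15800 ± 5412 CPM. nifH_2 had 2 reads in the 3 culture libraries together, and its ratio of 99150 has a 95% counting interval of 27450 to 818700. The ferredoxin gene fdxN_2 had 3 reads in culture, for a ratio of 5585 with an interval of 1911 to 27080. Intervals cover counting error only. The call for the nitrogenase list held in camera (adjusted p = 1.35e-37) and was not kept with an estimated correlation (adjusted p = 0.181).

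Single genes of dicarboxylate uptake and nitrogen regulation rose in E-type nodules, in lists that camera did not call, and the hydrogenase list was called. dctA1, a dicarboxylate transporter gene (5003356 to 5004675, minus strand), went from 4.66 ± 1.02 to 2666 ± 674 CPM, a log2 fold change of 9.2 ± 0.32 (adjusted p = 4.84e-09). In its list of dicarboxylate uptake and the tricarboxylic acid cycle, 10 of 23 genes rose and 5 fell, among them sdhA, a succinate dehydrogenase subunit gene that rose by 1.01 ± 0.14, and sucC, a succinyl-CoA ligase gene with a change of -1.08 ± 0.26. Of 21 hydrogenase genes 12 rose and 4 fell, among the latter HupA, a symbol also in use for a DNA-binding protein. The uptake hydrogenase subunit genes hupS and hupL rose by 6.5 ± 0.48 and 6.03 ± 0.48. The list was called in camera (adjusted p = 0.018), with an adjusted p = 0.964 with an estimated correlation. Of 15 genes for ammonium assimilation and nitrogen regulation 4 rose. These were glnII, a glutamine synthetase gene (3.6 ± 0.19), glnB, a PII signal protein gene (3.06 ± 0.22), the ammonium transporter gene amtB_2 (3.1 ± 0.15) and rpoN, for sigma factor 54 (2.44 ± 0.19). Another 5 fell, and glnA, another glutamine synthetase gene, was at 3302 CPM in culture and 2972 CPM in E-type nodules (adjusted p = 0.441; 0.0215 with total counts in place of TMM factors). The list's median was -0.13 and its mean 0.56. Of 9 multidrug efflux genes 7 rose and 2 fell (median 2, camera adjusted p = 0.0039, and adjusted p = 0.742 with an estimated correlation). The pump genes mdtA_2, mdtB_1 and mdtA_1 rose by 3.38, 2.84 and 2.74, and mexB and acrA changed by -2.15 and -1.36. Outside these lists, plcN_1, a phospholipase C gene (5732602 to 5734731, minus strand), rose from 21.3 ± 1.72 to 1975 ± 313 CPM, and cysE_1, a serine acetyltransferase gene of the amino acid list that lies at 1753018 to 1753809, rose by 10.33 ± 0.37.

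The photosynthesis genes had the lowest median of the lists. Of 31 genes 29 fell and 1 rose, with a median of -4.68 (camera adjusted p = 3.3e-21, and adjusted p = 0.181 with an estimated correlation). bchE, for a step of bacteriochlorophyll synthesis (5758605 to 5760209, minus strand), went from 2757 ± 1274 CPM in culture to 22.3 ± 6.46 CPM, a log2 fold change of -6.95 ± 0.49 (adjusted p = 4.1e-07). The other bch genes bchL, bchJ, bchF, bchX, bchN and bchC changed by -6.45, -6.31, -6.21, -6.12, -6.12 and -5.94. The reaction centre genes pufL and pufM changed by -5.4 and -4.23. In the denitrification list 7 of 14 genes fell and 2 rose. napA, for the periplasmic nitrate reductase, fell from 5304 ± 2904 to 90.4 ± 15.7 CPM, and nosR and nirK changed by -4.95 and -2.78. All but 1 of 16 chemotaxis genes fell, by at least 2-fold in each of the 15, with a median of -2.13 (camera adjusted p = 1.66e-05, and adjusted p = 0.742 with an estimated correlation). cheR_1, cheY_1 and cheA_1 changed by -3.79, -3.43 and -3.18. Ribosomal protein genes fell in 40 of 47 cases, with a median of -1.19 (camera adjusted p = 1.63e-07, and adjusted p = 0.742 with an estimated correlation). rpsR and rplM changed by -2.4 ± 0.24 and -2.08 ± 0.19. Of the 16 flagellar genes only flgI was called, at -1.84. That count depends on the library. Without E-type replicate 1 it came to 5 lower, without E-type replicate 3 to 7 higher and 1 lower, and with total counts in place of TMM factors to 5 lower.

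In the cell division and cell cycle list 10 of 22 genes fell and 5 rose. ctrA, a master regulator of the alphaproteobacterial cell cycle, fell from 2486 ± 121 to 610.1 ± 134 CPM, a log2 fold change of -2.03 ± 0.19. The replication initiator gene dnaA changed by -2.23 and the division gene ftsZ by -1.23, while minE, of the division site system, rose by 1.97 ± 0.49. Of 14 genes for microaerobic respiration and its regulators 4 rose and 3 fell. fixR_1, which joined the list by its symbol only and lies directly before nifA, rose by 7.62 ± 0.38. The regulator gene fixK_2 changed by -3.69, from 3568 to 277 CPM. Of the 7 tested cco genes of the list 1 rose and 1 fell. Genes of the nodulation list fell in 9 of 17 cases and rose in 3. The 3 that rose were nodD3, of a family of transcriptional regulators, and nolU and nolV, known from type III secretion clusters. The 17 also include the regulator genes nodD1, nodD2 and nolA. nodC and nodZ changed by -1.82 and -1.74, and nodA was at 66.5 ± 4.48 CPM in culture and 97.7 ± 37.6 CPM in E-type nodules (adjusted p = 0.0931; 0.0107 without E-type replicate 3). Of 20 chaperone genes 5 rose and 4 fell, and groL_1, for a GroEL chaperonin, changed by -1.84. In the list for defence against reactive oxygen 6 of 15 rose and 2 fell, with AhpC and ahpD, an alkyl hydroperoxide reductase pair, up by 3.51 and 3.42. The polyhydroxybutyrate genes fell in 3 of 4 cases, phbB at -2.53 and phbC at -1.58, while phbH rose by 1.25 ± 0.23. Of the 4 trehalose and glycogen genes that matched the general stress response list 3 rose, otsA by 3.22 ± 0.21; the list was not called in camera (adjusted p = 0.269). Of 23 iron and haem genes 8 rose and 8 fell. The 5-aminolevulinate synthase copies hemA_2, beside the bch genes, and hemA_3 changed by -4.46 ± 0.35 and 1.69 ± 0.19. The 16 calls became 9 without E-type replicate 1, 10 without E-type replicate 2 and 10 without culture replicate 2.

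Among the other lists, 28 of 88 amino acid synthesis genes rose and 34 fell, with metH and metY, of methionine synthesis, at -3.2 and -3.06. Of 29 nucleotide synthesis genes 7 rose and 7 fell, and purF, of purine synthesis, rose by 1.15. Of 23 ATP synthase and complex I genes 13 fell and 1 rose, and atpD changed by -0.91. Of 19 peptidoglycan genes 7 rose and 4 fell, with murA_1 up by 1.45. Of 16 polysaccharide genes 5 rose and 5 fell, and lpxC, of lipid A synthesis, changed by -1.25. Of 13 Calvin cycle genes 3 fell (5 with total counts in place of TMM factors), cbbR at -2.95, and 10 were not called, among them cbbL, for the large subunit of RuBisCO (63.1 ± 21.9 against 34.1 ± 15.4 CPM). Of 9 type III secretion genes 3 rose, rhcN, the secretion ATPase gene, by 1.17. The 9 include hrcA, known as a repressor of heat shock genes. Without E-type replicate 2 the list had 5 calls, 2 of them lower. Of the 4 tested trb genes, the only kind in the type IV and VI secretion list, 1 rose (2 without E-type replicate 1). trbE stood at 6.94 and 7.59 CPM. The hopanoid gene shc was at 113 ± 10.1 and 125 ± 14.7 CPM (adjusted p = 0.438). 

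RNA was extracted by different methods from culture and nodules, per the labels, in this and the next comparisons with culture. Over all genes 4246 of 6667 were called in E-type nodules against culture, 2118 higher and 2128 lower, of which 1427 and 1378 changed at least 2-fold. Adjusted over the list alone, ribosomal protein genes had 41 lower, hydrogenase genes 12 higher and 5 lower, amino acid synthesis genes 29 higher and 34 lower, chaperone genes 4 higher and 3 lower and Calvin cycle genes 2 lower. The counts of the other 22 lists, nitrogenase and photosynthesis among them, were the same as over all genes. Medians and means differed in sign for the amino acid (-0.02 and 0.01) and chaperone (-0.12 and 0.09) lists. Camera adjusted p for lists named here without one ran from 0.158 to 0.988. With total counts in place of TMM factors the median of all genes moved from 0.031 to -0.238, and the calls split into 1587 higher and 2554 lower.

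Another comparison set S-type bacteroids of A. indica nodules against the same culture. By the same count nifD again had the highest mean CPM of all genes tested. All 20 tested members of the nitrogenase list rose, with a median of 11.74 (camera adjusted p = 5.65e-31, and adjusted p = 0.285 with an estimated correlation). nifD reached 52700 ± 10500 CPM, a log2 fold change of 12.29 ± 0.49 (adjusted p = 6.76e-09). nifK, nifB, fixA, fixB and fixC rose by 11.31, 12.78, 12.81, 12.75 and 12.61, and nifA rose by 4.61 ± 0.39. nifH_1 reached 24090 ± 5126 CPM and nifH_2 11190 ± 1861 CPM, with the same uncertainty in the split of reads. The ratio of nifH_2 to culture was 67330, with a counting interval of 18640 to 556000, and that of fdxN_2 was 4838, with an interval of 1655 to 23460. Hydrogenase genes rose in 16 of 21 cases and fell in 2 (median 2.82, camera adjusted p = 0.000967, and adjusted p = 0.899 with an estimated correlation). hupS and hupL rose by 7 ± 0.48 and 6.5 ± 0.49. dctA1 rose by 7.59 ± 0.3, to 871 ± 146 CPM. All 4 genes matched to the general stress response list rose (camera adjusted p = 0.0286, and adjusted p = 0.731 with an estimated correlation). otsA, for trehalose 6-phosphate synthase (7100813 to 7102276, minus strand), went from 45.3 ± 1.69 to 2016 ± 549.5 CPM, and otsB and the glycogen debranching gene glgX_2 rose by 1.95 and 3.73. glnII, glnB, amtB_2 and rpoN rose by 3.17, 2.63, 2.54 and 3.23, and 6 other genes of their list fell, among them glnA at -1.24. The list's median was -0.25 and its mean 0.4.

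Ribosomal protein, photosynthesis and chemotaxis genes fell. Of 47 ribosomal protein genes 44 fell, 43 of them at least 2-fold, with a median of -2.31 (camera adjusted p = 1.35e-18, and adjusted p = 0.285 with an estimated correlation). rpsG, rplL and rpsR changed by -3.45 ± 0.18, -3.32 ± 0.16 and -3.48 ± 0.25. Photosynthesis genes fell in 28 of 31 cases and rose in 1, with a median of -5.43 (camera adjusted p = 2.82e-19, and adjusted p = 0.285 with an estimated correlation). bchL and bchE changed by -7.38 ± 0.44 and -6.86 ± 0.48, and bchF, pufL, bchC, pufA and bchX changed by -6.83, -6.81, -6.8, -6.49 and -6.21. Among the genes named by the rule napA had the lowest fold change, at 25.7 ± 3.94 CPM and a log2 fold change of -7.68 ± 0.52 (adjusted p = 2.27e-07). Of 14 denitrification genes 9 fell and 1 rose. All 16 chemotaxis genes fell at least 2-fold, with a median of -2.8 (camera adjusted p = 2.47e-06, and adjusted p = 0.614 with an estimated correlation), cheY_1 and cheA_1 at -4.85 and -4.76. Flagellar genes fell in 9 of 16 cases and rose in 3, with a median of -1.95 and a camera adjusted p of 0.117. flgI, fliF and fliG changed by -4.24, -3.81 and -3.8.

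Cell cycle genes fell in 13 of 22 cases and rose in 8, with dnaA, ctrA and ftsZ at -2.99, -2.27 and -1.79 and minE up by 1.69. Of 20 chaperone genes 11 rose and 5 fell. dnaJ rose by 1.63 ± 0.17, lon, for an ATP-dependent protease, by 1.66 ± 0.28 and dnaK by 0.86 ± 0.21, while groL_1 fell from 2109 ± 119.8 to 168 ± 53.7 CPM and groEL stood at -1.42. In the microaerobic list 5 of 14 rose and 3 fell, fixR_1 with a rise of 7.59 and fixK_2 at -3.3. Of its 7 tested cco genes 1 rose and 1 fell. Of 17 nodulation genes 4 rose and 9 fell, nodC at -1.95, while nodD3, nolU and nolV were again among those that rose and noeI rose by 1.22. Of 15 genes for defence against reactive oxygen 7 rose and 4 fell, ahpD with a rise of 3.69 and the catalase-peroxidase gene katG at -1.72. Of 23 iron and haem genes 12 rose and 6 fell, and exbB_1 rose by 2.79. The 23 include hutU, hutH, hutI and hutC, known from histidine breakdown. Of 9 efflux genes 5 rose and 2 fell, mdtA_2 with a rise of 2.73 and mexB at -2.85. Of 4 polyhydroxybutyrate genes 3 fell, phbB at -3.37. Of 23 genes for dicarboxylate uptake and the tricarboxylic acid cycle 10 rose and 6 fell, and sdhA rose by 1.63. Of 23 ATP synthase and complex I genes 1 rose and 11 fell, atpC at -2.03 and atpD at -1.92. In amino acid synthesis 27 of 88 rose and 33 fell, aroK_2 with a rise of 3.82, and in nucleotide synthesis 7 of 29 rose and 10 fell, carB at -1.36. Peptidoglycan genes rose in 8 and fell in 4 of 19 cases, and polysaccharide genes in 5 and 5 of 16. Of 9 type III secretion genes 1 rose (hrcA, by 2.8) and 2 fell (4 with total counts in place of TMM factors), and rhcN stood at 97.3 ± 21.8 CPM (adjusted p = 0.138; 0.0493, higher, with the filter of 50 CPM in 3 libraries). Of the 4 tested trb genes of the type IV and VI secretion list 1 rose and 1 fell. shc stood at 139 ± 19.3 CPM (adjusted p = 0.108; 0.0212, higher, with the same filter). Of 13 Calvin cycle genes 4 fell, cbbT_1 at -1.72. Without S-type replicate 2 the number was 10, and the log2 fold change of cbbL, called in neither comparison with all libraries, moved from -0.79 to -2.48 (adjusted p = 0.00105).

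S-type nodules had 4638 genes called against culture, 2429 higher and 2209 lower, with 1712 and 1579 changed at least 2-fold. Adjusted over the list alone, efflux genes had 6 higher and 2 lower, microaerobic genes 5 higher and 2 lower and genes against reactive oxygen 8 higher and 4 lower, and the counts of the other 24 lists were the same as over all genes. Medians and means differed in sign for the amino acid (-0.06 and 0.02) and polysaccharide (0.27 and -0.03) lists. The type III secretion list had a median of -0.27 and a mean of -0.11, with a camera test in the upward direction. Lists given here without a camera p had adjusted p from 0.0992 to 0.989. With total counts in place of TMM factors the median of all genes moved from 0.07 to -0.144, and the calls split into 2002 higher and 2465 lower.

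For the mean of both bacteroid types against culture, 4738 genes were called, 2435 higher and 2303 lower, with 1552 and 1467 changed at least 2-fold. With total counts the split was 1862 higher and 2669 lower, and the median of all genes moved from 0.057 to -0.182. Both types shared 1708 genes called higher than culture and 1721 called lower, 3429 in all, nifD, hupL, dctA1, glnII and otsA among the former and bchE, napA, cheA_1, rpsG and ctrA among the latter. Independent lists of the same lengths would share 772 and 705. The log2 fold changes of the 2 comparisons correlated across genes with r = 0.911 and a covariance of 4.03. In 20 simulations all 9 libraries were drawn anew from the culture means, with no gene changed and the culture libraries shared by both comparisons. The mean r was 0.521, the mean covariance 0.048 and the mean number of shared calls 0. The simulations called a mean of 0.3 (E-type) and 0 (S-type) genes. Their 0 shared calls were thus fixed in advance and give no chance level for the overlap. The covariance above the simulated one was 3.982. The 3 culture libraries cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared culture libraries. Another 107 genes were called in opposite directions against culture, and all 107 were called between the bacteroid types.

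**Figure D2:**
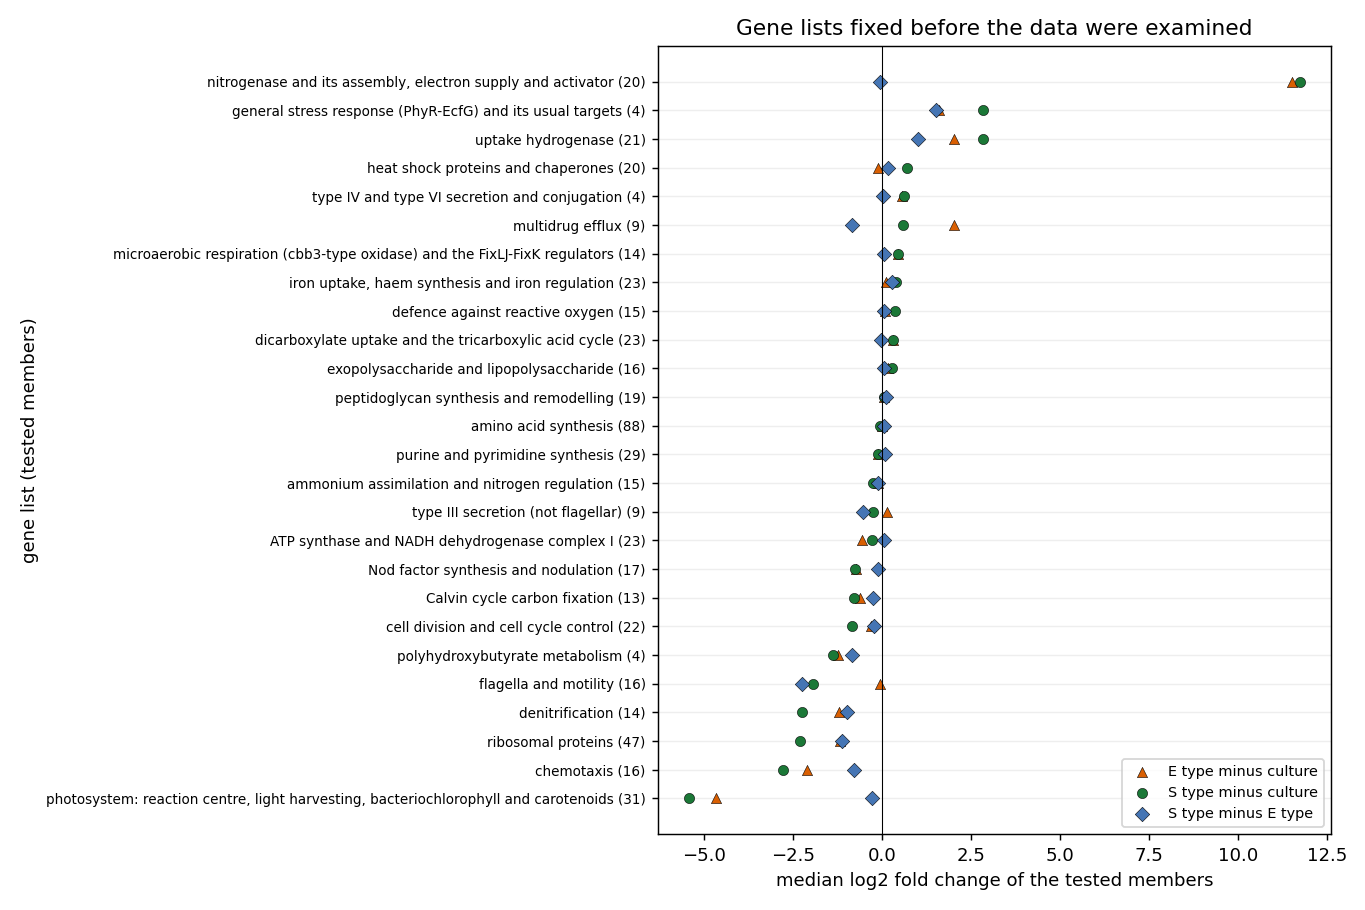
Median log2 fold change (x axis) of the tested members of 26 gene lists (y axis, tested members in parentheses), for E-type minus culture (triangles), S-type minus culture (circles) and S-type minus E-type (diamonds). Nitrogenase genes stand at 11.5 and 11.74 against culture and at -0.06 between the bacteroid types, and ribosomal protein genes at -1.19, -2.31 and -1.14.

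A further comparison set the 2 bacteroid types, each from 1 host species, against each other. Their nitrogenase genes stood close together. Of 20 tested members 19 were not called and 1, nifS_2, was higher in S-type nodules by 0.76 ± 0.14. nifD differed by -0.05 ± 0.3 (adjusted p = 0.907) and nifH_1 by -0.32 ± 0.27 (adjusted p = 0.365). Leaving out 1 library gave at most 4 calls, without E-type replicate 1 (4 higher) or E-type replicate 3 (1 higher, 3 lower, nifH_2 among them at -0.74), and 2 without S-type replicate 3. Ribosomal protein genes were lower in S-type nodules in 39 of 47 cases, with a median of -1.14 (camera adjusted p = 2.61e-17, and adjusted p = 0.798 with an estimated correlation). rpsG, rpsJ and rplL differed by -2.03 ± 0.17, -1.94 ± 0.17 and -1.78 ± 0.15. rpoB, for the beta subunit of RNA polymerase (2730500 to 2734618, plus strand), was at 3917 ± 92.5 CPM in culture, 6460 ± 493 CPM in E-type and 1809 ± 172 CPM in S-type nodules, a difference between the nodules of -1.84 ± 0.17 (adjusted p = 1.94e-05). Flagellar genes were lower in S-type nodules in 9 of 16 cases and higher in 2 (median -2.26, camera adjusted p = 0.00772, and adjusted p = 0.963 with an estimated correlation). flgG, a rod gene at 2132724 to 2133512, was at 115 ± 9.94 CPM in culture, 145 ± 39.2 in E-type and 13.5 ± 2.39 in S-type nodules. fliG and flgH differed by -3.4 ± 0.48 and -3.11 ± 0.29. Efflux genes were lower in S-type nodules in 8 of 9 cases (median -0.84, camera adjusted p = 4.82e-05, and adjusted p = 0.798 with an estimated correlation), with mdtB_1, mdtA_1 and mdtC at -2.48 ± 0.16, -2.16 ± 0.19 and -1.58 ± 0.18.

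Several named genes stood far below their E-type level. asd_1, for aspartate-semialdehyde dehydrogenase (3349668 to 3350693, minus strand), went from 63.1 ± 4.23 CPM in culture to 667 ± 18.1 CPM in E-type and 16.5 ± 0.422 CPM in S-type nodules, a difference of -5.33 ± 0.14 (adjusted p = 6.63e-09). sufC_2, sufS_2 and sufD_2, of an iron-sulfur cluster assembly system, stand side by side between 3744946 and 3748288 and differed by -4.71 ± 0.17, -4.21 ± 0.16 and -4.02 ± 0.17. Each was above culture in E-type nodules and below culture in S-type nodules. czcA_1, for a heavy metal efflux pump, was at 589 ± 21.9 CPM in E-type and 29.0 ± 6.65 CPM in S-type nodules (-4.32 ± 0.19). plcN_1 differed by -3.62 ± 0.19, and dapA_1, of diaminopimelate synthesis, by -3.7 ± 0.35. aroG, of aromatic amino acid synthesis, differed by -2.33 ± 0.2, and dctA1 by -1.61 ± 0.22.

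Other genes stood higher in S-type nodules. nhr3 (5411509 to 5412714, plus strand) was at 17.9 ± 2.72 CPM in culture, 15.4 ± 0.358 CPM in E-type and 2367 ± 715 CPM in S-type nodules, a difference of 7.27 ± 0.29 (adjusted p = 9.37e-08). The glycerol 3-phosphate dehydrogenase gene glpD_3 differed by 3.2 ± 0.16, aroK_2, a shikimate kinase gene, by 2.78 ± 0.36, the biotin synthesis genes bioB and bioF by 2.73 ± 0.24 and 2.44 ± 0.26, the molybdate permease gene modB by 2.69 ± 0.21, the potassium pump gene kdpB by 2.52 ± 0.34 and the cold shock gene cspA_1 by 2.49 ± 0.35. bioB and bioF were below culture in E-type nodules and above culture in S-type nodules. Of the 4 genes matched to the general stress response list 3 were higher (median 1.5, camera adjusted p = 0.0123, and adjusted p = 0.925 with an estimated correlation), otsA by 2.26 ± 0.2 and glgX_2 by 2.23 ± 0.37. Hydrogenase genes were higher in 8 of 21 cases (median 1, camera adjusted p = 0.0108, and adjusted p = 0.963 with an estimated correlation), hupG by 1.91 ± 0.31. The count fell to 4 without E-type replicate 1, E-type replicate 2, S-type replicate 2 or S-type replicate 3, and reached 13 without S-type replicate 1. Of 20 chaperone genes 8 were higher and 4 lower. dnaJ and hslU were higher by 2.3 ± 0.17 and 1.28 ± 0.16, and groL_1 and groEL lower, at -1.81 ± 0.23 and -1.26 ± 0.18.

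**Figure D3:**
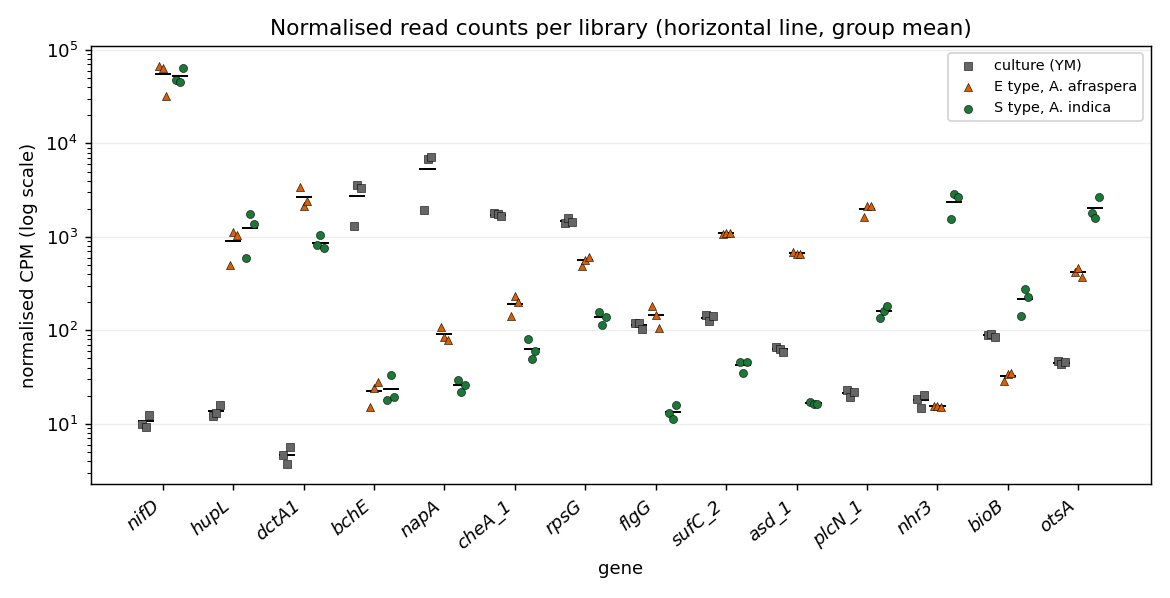
Normalised CPM (y axis, log scale) of 14 named genes (x axis) in each of the 9 libraries, as 3 points per group with the group mean as a horizontal line. For asd_1 the means are 63.1 in culture, 667 in E-type and 16.5 in S-type nodules, and for nhr3 they are 17.9, 15.4 and 2367.

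Photosynthesis genes were lower in S-type than in E-type nodules in 6 of 31 cases, pufB at -2.3 ± 0.32 and pufA at -1.81 ± 0.28, and in 11 without E-type replicate 1. Of 16 chemotaxis genes 6 were lower and 2 higher, cheA_1 at -1.58 ± 0.23. The 8 calls became 5 without E-type replicate 2, E-type replicate 3 or S-type replicate 3 and 3 without S-type replicate 1. Of 13 Calvin cycle genes 3 were lower and 1 higher, cbbT_1 at -1.66 ± 0.14 and cbbG at -1.38 ± 0.13. Without S-type replicate 2 there were 10 lower and 1 higher, and cbbL moved from 0.1, not called, to -1.60 (adjusted p = 0.0245). In the nitrogen regulation list 5 of 15 were lower, glnA at -1.09 ± 0.17, and 2 higher, rpoN at 0.79 ± 0.18. Cell cycle genes were lower in 5 and higher in 4 of 22 cases, pleD and ftsW at -1.08 ± 0.14 and -1.67 ± 0.34. Of 23 iron and haem genes 7 were higher, hemE by 1.1 ± 0.14, and 4 without E-type replicate 2 or S-type replicate 2. Of 14 denitrification genes 4 were lower, napA at -1.81 ± 0.41, and 2 without E-type replicate 3, S-type replicate 1 or S-type replicate 3. Nucleotide synthesis genes were higher in 3 and lower in 6 of 29 cases, guaB and ndk at -1.22 ± 0.16 and -1.42 ± 0.14. Amino acid synthesis genes were higher in 20 and lower in 14 of 88 cases, peptidoglycan genes in 5 and 2 of 19, and ATP synthase and complex I genes in 3 and 4 of 23, atpD among the latter at -1.01 ± 0.17. In the tricarboxylic acid cycle list 6 of 23 were higher, sdhA by 0.61 ± 0.14, and 4 lower. Its 10 calls became 4 without E-type replicate 2, 6 without S-type replicate 2 and 5 without S-type replicate 1 or S-type replicate 3. Of 15 genes against reactive oxygen 1 was higher and 3 lower, katG at -0.87 ± 0.15. The 4 calls became 2 without E-type replicate 1, E-type replicate 2 or S-type replicate 2 and 1 without S-type replicate 3. Of 4 polyhydroxybutyrate genes 3 were lower, phbH at -1.34 ± 0.23, and 1, phbC, higher by 0.6 ± 0.14. There were 2 calls without S-type replicate 1 or S-type replicate 3. Of 17 nodulation genes 3 were higher, noeI by 1.34 ± 0.21, and 2 lower, among them the regulator gene nodD1 at -0.97 ± 0.23. There were 3 calls without E-type replicate 1 or S-type replicate 2. Of 16 polysaccharide genes 1 was higher and 2 lower, rfbE at -2.41 ± 0.36, with 5 calls without S-type replicate 1. Of 9 type III secretion genes 1, hrcA, was higher and 2 were lower, rhcN at -0.81 ± 0.21, with 6 calls without E-type replicate 3. Of 14 microaerobic genes 1 was higher and the count was 0 without E-type replicate 2. None of the 4 tested trb genes of the type IV and VI secretion list was called by edgeR. The count was 1 without E-type replicate 1, without S-type replicate 2 or with DESeq2 size factors. shc differed by 0.16 ± 0.16 (adjusted p = 0.456). These lists had camera adjusted p from 0.12 to 0.945.

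Between the bacteroid types 2555 genes were called, 1275 higher and 1280 lower in S-type nodules, with 549 and 717 changed at least 2-fold. The split was 1142 higher and 1395 lower with DESeq2 size factors, and 1305 higher and 1088 lower with total counts. By the stricter rule of an adjusted p under 0.01 and a log2 fold change of at least 1.5, 207 were higher and 328 lower. Adjusted over the list alone, ribosomal protein genes had 39 lower and efflux genes 8 lower, as over all genes, hydrogenase genes had 11 higher and flagellar genes 9 lower and 3 higher. By the same adjustment photosynthesis genes had 5 lower, denitrification genes 3 lower, iron and haem genes 6 higher, microaerobic genes 0, and the tricarboxylic acid cycle list 6 higher and 5 lower. The nitrogen regulation and nucleotide lists each had 2 higher and 6 lower, ATP synthase and complex I genes 2 higher and 4 lower, genes against reactive oxygen 1 higher and 2 lower, and type III secretion genes 1 higher and 1 lower. Medians and means differed in sign for the nitrogenase (-0.06 and 0.03), ATP synthase (0.04 and -0.05), nucleotide (0.08 and -0.1), reactive oxygen (0.06 and -0.09), polysaccharide (0.06 and -0.11) and secretion type IV and VI (0.02 and -0.24) lists, and the nodulation list had a median of -0.11 and a mean of 0. Genes raised in 1 bacteroid type against both other groups numbered 1382, of which 923 were raised in S-type and 459 in E-type nodules, otsA and plcN_1 among them.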

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

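The tests of bacteria with the culture's expression and of unequal depth were chosen only after the results were seen. The following results differed between the 2 bacteroid types, by the edgeR or camera test of the difference itself, or came from reads not used in the comparisons. No test for single outlying libraries was run, and values without a library stand beside the results that it changes.

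Median log2 differences, S-type minus E-type, were -0.84 for efflux genes and -2.26 for flagellar genes. They were 1.5 for the trehalose and glycogen genes of the general stress response list, 1 for hydrogenase genes and -1.14 for ribosomal protein genes. All 5 lists were called by camera at its preset correlation and none was called when the correlation was estimated. In the same order, camera with an estimated correlation gave adjusted p of 0.798, 0.963, 0.925, 0.963 and 0.798. In fry the flagellar and hydrogenase lists were not called (adjusted p = 0.103 for each). The efflux, general stress response and ribosomal protein lists were called in fry (adjusted p = 0.00118, 0.00608 and 0.000607). In all, 107 genes were called in opposite directions against culture in the 2 types. The single genes given here are named genes of that kind. asd_1 stood at -5.33, sufC_2 at -4.71, czcA_1 at -4.32, sufS_2 at -4.21, sufD_2 at -4.02, rfbE at -2.41, rpoB at -1.84 and ndk at -1.42. bioB stood at 2.73, bioF at 2.44, dnaJ at 2.3 and hslU at 1.28. The rise of ndk in E-type nodules against culture was not called with total counts (adjusted p = 0.428), without culture replicate 2 (0.0675) or 3 (0.0968), or without E-type replicate 1 (0.0778) or 2 (0.0583). The fall of rfbE in S-type nodules against culture was not called without culture replicate 1 (adjusted p = 0.0872). Reads of nifH_1 and nifH_2 that map to more than 1 place, left out of the comparisons, came to at least 10760 CPM in each nodule library and at most 2.53 CPM in culture.

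Ribosomal protein genes were lower in S-type than in E-type nodules, with 39 of 47 called. A candidate explanation is that E-type nodules also held bacteria with the culture's expression. For that, culture-type RNA would have to make up a median of 26.6% (quartiles 20.2 to 36.2) over 46 ribosomal genes, while 25 photosynthesis genes kept a median of 3.08% of their culture level in E-type nodules (quartiles 1.69 to 5.44), which argues against it. Short genes being counted less in S-type libraries is argued against by 10000 lists of genes matched on length and expression, whose medians had a median of 0.02 and a lowest value of -0.49. After thinning to equal depth the median was -1.13 and 38 genes were still called lower. Thinning keeps each gene's expected share of its library, so the median could hardly move and does not decide on unequal depth. With DESeq2 size factors and with total counts 39 and 37 were lower. Bacteria in nodules with an expression unlike the culture's, and the host or bacteroid type, stay open and were not tested.

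Of 16 flagellar genes 9 were called lower in S-type than in E-type nodules, 2 higher and 5 neither, with a median of -2.26 over all 16. For the 9 lower genes the same candidate explanation would need a median of 93.4% culture-type RNA, and for the 10 of all 16 that were above S-type nodules in culture 83.6% (quartiles 61 to 129.8), against the 3.08% that photosynthesis genes kept, which argues against it. After thinning the whole list had a median of -2.11, with 9 called lower and 3 higher. Thinning keeps expected shares, so this median does not decide on unequal depth. The whole list had 9 lower and 2 higher with DESeq2 size factors (median -2.31), and 9 lower and 4 higher with total counts (median -2.17). Bacteria unlike the culture, and the host or bacteroid type, stay open and were not tested.

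Other splits of the libraries were counted for each test. Splits of 6 libraries, 3 against 3, number 10 and are too few for a share under 0.05. In fits of the 6 libraries of a pair of groups alone, 1 split gave as many genes in each pairwise comparison, with real values of 4218, 4704 and 2157 (4246, 4638 and 2555 in the fit of all 9) and a highest other value of 0. For list members called, 1 split gave as many, with real values of 351, 398 and 188 and a highest other value of 0. For lists called by camera, 10, 10 and 8 of the 10 splits gave as many, with real values of 6, 6 and 6 and highest other values of 10, 9 and 11. For both bacteroid types against culture, refitted with 2 groups (3934 genes, against 4738 with 3 groups), 1 of 84 splits gave as many (highest other 1381), which excludes a chance division of these libraries. For genes shared by both comparisons it was 1 of 100 drawn splits (3429, highest other 3028), which excludes the same at a share of 0.05. For genes raised in 1 type against both other groups it was 2 of 100 (1382, highest other 1470). The drawn splits mixed culture with nodule libraries. They therefore do not decide on a chance division between E-type and S-type libraries, on which the last count rests. The labels do not say that replicates are separate cultures or plants, so these counts do not exclude chance differences between cultures or plants.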

How the results depend on the processing

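The alternative that includes reads mapped to more than 1 place was chosen after seeing the data. The stricter threshold was not applied to single named genes. Over the other alternatives 4837 of 4913 called values of named genes kept their direction and side of the threshold. The other 76 were no longer called, 47 values not called before became called and 1 reversed. Named genes were mainly picked for large changes in these same data, and each is counted again over the alternatives. The share that was kept therefore does not measure how stable other genes are. List counts were taken only for DESeq2 size factors, total counts, no filter, the replicate block, all gene reads and each left-out library. Of these 891 list counts 841 stayed within 1.5 times. Without S-type replicate 2, cbbL between the bacteroid types went to -1.601, and leaving out other libraries gave up to 0.557. The filter of 50 CPM in 3 libraries, which tests fewer genes, gave 2624 genes for E-type, 2824 for S-type and 2863 for both types against culture, and 2227 shared. The stricter threshold gave 1757, 2216 and 535 for the pairwise comparisons, 1925 for both types against culture, 1415 shared and 268 raised in 1 type, by construction. Camera called 6, 6 and 5 lists, 0, 0 and 0 with an estimated correlation, and fry, which does not compare a list with other genes, 15, 19 and 6. The camera runs differ only in the correlation, estimated at 0.274 to 0.809 for the called lists against the preset 0.01. The preset p-values thus take members as more independent than estimated, and other splits of the libraries called as many lists. The cause of the difference with fry was not tested. Leaving out single libraries gave 3784 to 4064 genes for E-type, 4207 to 4444 for S-type, 2106 to 2503 between types, 4214 to 4703 for both types, 3076 to 3341 shared and 1140 to 1332 raised in 1 type. The replicate block gave 4058, 4513 and 2317, with 15 hydrogenase genes higher in S-type nodules in place of 8. None of 9 pairs of libraries with the same number had deviations correlated over 0.1 (-0.282 to 0.082), and 0 libraries correlated best with their own number. Across all genes the numbers thus gave no sign of pairing. Pairing in single genes or lists is not excluded, as hupL was lowest in replicate 1 of each group. Thinning to the shallowest library gave 3966, 4404 and 2275, fewer than with all reads. A greater depth was not tested. The alternative with structural RNA kept was not run, since the files used here hold coding genes only.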

Other observations

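The gene families here were chosen after their values were seen. The test of neighbouring genes was written before its result was seen. Cobalamin synthesis genes (symbols cob) had 15 of 20 lower in E-type nodules than in culture and 1 higher, with a median log2 fold change of -1.82 (camera adjusted p = 0.000248, and adjusted p = 0.686 with an estimated correlation). In S-type nodules 8 were lower than in culture and 2 higher, with a median of -0.38 (camera adjusted p = 0.756). Between the bacteroid types 15 were higher in S-type nodules and 0 lower, with a median of 1.43 (camera adjusted p = 1.76e-09, and adjusted p = 0.618 with an estimated correlation). All 11 suf genes, of iron-sulfur cluster assembly, were above culture in E-type nodules (median 3.02), while in S-type nodules 7 were above and 4 below (median 1.81). Between the bacteroid types 5 of the 11 were lower in S-type nodules, 0 higher and 6 not called, with a median of -0.11 (camera adjusted p = 7.18e-10, and adjusted p = 0.618 with an estimated correlation). The potassium pump genes kdp were higher in S-type than in E-type nodules in 4 of 5 cases (median 2.03, camera adjusted p = 0.0203, and adjusted p = 0.954 with an estimated correlation). The amino acid transporter genes aap were lower in 5 of 5 (median -1.22, camera adjusted p = 0.00981, and adjusted p = 0.618 with an estimated correlation). Of 81 families of at least 5 tested genes, camera called 11 for E-type and 10 for S-type nodules against culture and 11 between the types. Those called between the types and not given here are mdt, flg, rpo, glt, hup, rpl and rps. No family was called in any comparison when the correlation was estimated, with the lowest adjusted p = 0.397 with an estimated correlation.

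Some of the genes that differed between the bacteroid types stood side by side. Of the 1266 genes called with at least a 2-fold difference, 285 lay in 47 runs of at least 4 neighbours that changed the same way, 30 lower and 17 higher in S-type nodules, and the highest of 1000 shuffled gene orders held 20 such genes. That value argues against a spread of single genes at random along the gene order. Shuffling moves each gene alone, so neighbours transcribed together would exceed it in any comparison. The result is therefore not particular to the bacteroid types. The longest runs were 21 genes from rpsL to rplF (2745636 to 2757764, median -1.52) and 16 genes from cobU to bluB (2248294 to 2264377, median 1.69). The 6 genes from sufA to sufB_2 (3744127 to 3749904) had a median of -3.86, and the 8 genes at 5126084 to 5134173 a median of 3.98.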
